A study of Mus musculus with 15 samples.

How the data were processed

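The study measured RNA of single cells from mouse amygdala in 15 libraries, 3 for each of 5 groups: sound-only control at 2 h, fear conditioning at 2 h and at 5 d, and reward conditioning at 2 h and at 5 d. The deposited values are UMI counts per gene and cell barcode, made by the authors with Cell Ranger 7.0.1 on mm10 with mCherry, EGFP and EYFP sequences added, as deposited and per the file headers. Each file held called barcodes alone, with at least 500 UMIs each. Whether introns were counted is not stated. The suspension was pooled, and the labels do not state how many animals made up a library. Gene positions came from an mm10 annotation that matched 32158 of 32288 gene identifiers (99.6%).

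Libraries held 59133807 to 127213006 UMIs (median 74036088) in 7605 to 29673 barcodes, with a median of 1071 to 6452 UMIs per barcode. Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept (208334 of 248383). Scrublet in scanpy 1.11.5 (expected doublet rate 0.08, 30 principal components) removed 12932 doublets, 4.61% to 8.90% per library, and left 195402 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, seed 1) gave 36 clusters without batch correction. A cluster of at least 50 cells was named when at least 3 markers of a cell type were found in 20% of its cells at a log2 level 1 or more above other cells. This rule was set after the clusters had been seen; 29 clusters were named. The other 7 were left out of the class tests: 4 had fewer than 50 cells, 2 had fewer than 3 markers and 1 had more leading genes of another class. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

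Counts were summed per class and library where at least 20 cells were present. In R 4.3.3, edgeR 4.0.16 was fitted to all 15 libraries (TMM normalization, filterByExpr, robust quasi-likelihood), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called in 8 comparisons for excitatory neurons and 4 against the control for inhibitory neurons, astrocytes, oligodendrocytes and microglia. Replicate libraries of excitatory neurons correlated at 0.966 to 0.993 in log CPM. In simulated data made from these counts with 200 changed genes, the excitatory neuron test called 28.6% of genes changed by a log2 of 1, 80% of those changed by 2, and 3 unchanged genes. A gene was called separated when all 3 values of one group lay above all 3 of the other.

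For 24 lists of genes written before the data were examined, camera (limma 3.58.1, preset correlation 0.01) tested each list with at least 5 tested members, with one adjustment over the 532 planned tests. The lists were immediate early, late activity-response, excitatory synapse, inhibitory synapse, memory signalling and chromatin, cytosolic ribosomal protein, nuclear oxidative phosphorylation, mitochondrially encoded, heat shock and dissociation stress, glucocorticoid-responsive, circadian clock, neuropeptide, neuromodulator receptor, myelin, cholesterol synthesis, homeostatic microglia, reactive microglia and cytokine, interferon-response, reactive astrocyte, astrocyte transport and coupling, choroid plexus, blood cell, striatal projection neuron and basolateral excitatory subtype genes. Members were counted over all genes and adjusted over the list alone.

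Genes were named by a fixed rule. It took the 8 largest separated calls per direction and comparison, with predicted genes only counted, and up to 4 called members per list and direction. Fos, Arc, Npas4, Bdnf and Fkbp5 in neurons, Gfap and Fkbp5 in astrocytes, Mbp and Fkbp5 in oligodendrocytes and P2ry12 and Apoe in microglia were always included. Where fewer than 5 genes passed, the 5 smallest p-values were taken as not past the threshold.

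Class shares and shares of neurons with a UMI of Fos, Arc or Npas4 (cells thinned to 2000 UMIs, smaller cells left out) were compared between groups by permutation with 100000 draws, and pairs of groups by exact permutation, whose smallest p for 3 against 3 is 0.1. Changes after fear and reward share their controls, so their covariance was set against 50 simulations of unchanged groups. Reporter labels needed at least 1 UMI, and labelled and unlabelled neurons of a library were compared in edgeR with the library as a block, with 24 exchanges of the labels within libraries. The labels do not state which reporter marks which projection.

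Alternatives planned for genes were RLE normalization, DESeq2 1.42.0, no low-count filter, only the 6 libraries compared, a replicate block, doublets kept, at least 1000 genes per barcode and leaving out each library. For lists they were an estimated correlation, fry and a replicate block, for shares thinning to 1000 UMIs or no thinning, and for labels at least 2 UMIs. Chosen after the data had been seen were the largest cluster of a class alone, leaving out 2 controls rich in low-UMI barcodes, 2 surrogate variables (sva 3.50.0), labels above the level that about 1 in 1000 oligodendrocytes exceeds, the replicate block with an estimated correlation, tests of the change with time after fear less that after reward with 100 redraws, and comparisons of endothelial cells, labelled neurons and glia between conditioned groups. The groups, comparisons, tests and first set of alternatives were fixed before the data were examined.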

Results

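Single-cell RNA was counted in 15 libraries of mouse amygdala, a brain region that links sounds and places to threat and reward. Mice heard sounds alone (control), or learned that a sound foretold an aversive or a rewarding outcome (fear or reward conditioning). Tissue was taken 2 h or 5 d after conditioning and, for the control, at 2 h only. There were 3 libraries in each of 5 groups: control, fear at 2 h, fear at 5 d, reward at 2 h and reward at 5 d. Retrograde viruses had marked amygdala neurons that project to the nucleus accumbens or to the auditory and temporal association cortex. The deposited counts held 248383 cell barcodes, from 7605 to 29673 per library, and between 59133807 and 127213006 unique molecular identifiers (UMIs) per library. The labels do not state separate animals, so p-values describe only these samples. Camera's preset correlation treats list genes as near independent. Group values are means ± SD of 3 libraries in CPM (UMIs scaled by the library total of the class), log2 changes are given ± SE, and gene positions are on the mm10 assembly.

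After filtering, 195402 cells remained and 174117 of them fell into 29 clusters named from marker genes, in 14 classes. Astrocytes (30839 cells), oligodendrocytes (28252), excitatory neurons (26176), inhibitory neurons (23526), oligodendrocyte precursors (23121), microglia (21240) and endothelial cells (11143) were the most numerous. Each library gave between 985 and 2876 excitatory neurons, which held 11864571 to 54718938 UMIs. Excitatory neurons made up 11.9% ± 0.964 of cells in the control, 9.42% ± 2.34 at 2 h after fear, 18.3% ± 7.99 at 2 h after reward, 15.1% ± 5.04 at 5 d after fear and 14.6% ± 3.01 at 5 d after reward. No class share passed the test between groups (lowest adjusted permutation p = 0.536). Leaving out fear 5 d replicate 2 brought the share of mural cells to an adjusted permutation p of 0.0404, and leaving out control replicate 1 brought that of unnamed cells to 0.0437. Unnamed cells with few UMIs formed 34.2% of control replicate 2 and 20.2% of control replicate 3, against 1.16% of control replicate 1 and at most 12% elsewhere.

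Excitatory neurons at 2 h after fear conditioning were set against the control to ask what differs soon after aversive learning. Nuclear genes of oxidative phosphorylation, which make ATP in mitochondria, rose as a list, with 74 of 75 members higher by a median log2 change of 1.12 (camera adjusted p = 4.38e-50, 0.402 with estimated correlation). Atp5j2, a subunit of the ATP synthase, had 276 ± 129 CPM against 84.7 ± 16.7 (log2 1.70 ± 0.32; edgeR adjusted p = 0.175), and Ndufs5 of complex I had 281 ± 147 against 87.0 ± 20.4 (log2 1.69 ± 0.33). Cytosolic ribosomal protein genes rose by a median of 0.65, with 72 of 74 higher (camera adjusted p = 5.71e-31, 0.407 with estimated correlation). Genes of memory signalling and chromatin, such as kinases and histone deacetylases, fell by a median of 0.15, with 23 of 25 lower (camera adjusted p = 0.000259, 0.407 with estimated correlation). The immediate early genes, which neurons switch on within minutes of firing, gave no call: Fos differed by -0.06 ± 0.28, Arc by -0.11 ± 0.39 and Npas4 by 0.05 ± 0.24. Bdnf, a growth factor of late activity, differed by -0.23 ± 0.32, and the stress-hormone target Fkbp5 by 0.00 ± 0.14. Heat shock and dissociation stress genes rose by 0.28 in 17 of 21 members (camera adjusted p = 0.0197, 0.652 with estimated correlation), 1 with p adjusted over the list alone, a call lost without control replicate 1 or 2 or fear 2 h replicate 3 (up to p = 0.377). Haemoglobin genes rose by a median of 5.6 in all 5 members (camera adjusted p = 0.0342, 0.609 with estimated correlation), a call lost without control replicate 2 or 3 or fear 2 h replicate 1 or 2 (up to p = 0.404). The rise rests on fear 2 h replicate 2, with 282 CPM in sum against 14.5 and 3.54 in replicates 1 and 3 and 4.49 to 7.81 in the controls. Of 19027 genes tested with edgeR, 0 passed, 1996 had an unadjusted p under 0.05 and DESeq2 called 304. Adjusted over the list alone, 64 oxidative phosphorylation and 47 ribosomal genes passed, and without fear 2 h replicate 2 the edgeR count was 466.

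At 2 h after reward conditioning, the same comparison asks what differs soon after appetitive learning. Immediate early genes fell in excitatory neurons by a median of 0.47, with 24 of 26 lower (camera adjusted p = 8.39e-10, 0.402 with estimated correlation). Npas4, an activity-induced transcription factor (chromosome 19, 4984355 to 4990316), had 7.69 ± 1.23 CPM against 20.9 ± 3.25 (log2 -1.43 ± 0.24; edgeR adjusted p = 0.296). Arc, which shapes synapses (chromosome 15, 74669083 to 74672570), had 7.89 ± 3.05 CPM against 28.9 ± 12.6 (log2 -1.84 ± 0.40; edgeR adjusted p = 0.471). Fos differed by -0.63 ± 0.28, Bdnf by -0.14 ± 0.32 and Fkbp5 by -0.06 ± 0.14. Genes encoded in the mitochondrial genome, whose level also tracks RNA quality, fell beside them by a median of 1.18 in 13 of 13 members (camera adjusted p = 5.33e-11, 0.416 with estimated correlation). Genes of cholesterol synthesis fell by a median of 0.35, with 16 of 17 lower (camera adjusted p = 1.17e-07, 0.407 with estimated correlation). Nuclear oxidative phosphorylation genes rose by a median of 0.68, with 74 of 75 higher (camera adjusted p = 3e-26, 0.506 with estimated correlation). When adjusted over the list alone, 4 immediate early, 10 mitochondrially encoded, 4 cholesterol and 0 oxidative phosphorylation genes passed. By edgeR 0 genes passed over all genes tested, with 1849 at unadjusted p under 0.05 and 26 called by DESeq2. The edgeR count was 2 when the other 9 libraries were left out of the fit.

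At 5 d after fear conditioning, excitatory neurons were set against the control to ask what differs once a memory has had time to settle. The control was taken at 2 h, so time since the session differs too. Immediate early genes fell by a median of 0.55, with 24 of 26 lower (camera adjusted p = 4.62e-10, 0.402 with estimated correlation). Fosb, a partner of Jun in the AP-1 factor, had 10.7 ± 2.02 CPM against 29.1 ± 8.84 (log2 -1.44 ± 0.26; edgeR adjusted p = 0.140). Fos differed by -1.02 ± 0.29, Arc by -1.10 ± 0.39, Npas4 by -0.58 ± 0.24 and Bdnf by -0.49 ± 0.32. Glucocorticoid-responsive genes fell by a median of 0.23, with 12 of 15 lower (camera adjusted p = 0.00258, 0.465 with estimated correlation). Fkbp5 among them had 24.4 ± 1.74 CPM against 41.4 ± 6.09 (log2 -0.76 ± 0.14; edgeR adjusted p = 0.140). Pde10a, a phosphodiesterase abundant in striatal neurons, had 228 ± 31.5 CPM against 439 ± 58.7. Mitochondrially encoded genes fell by a median of 0.87 in 13 of 13 members (camera adjusted p = 0.000115, 0.648 with estimated correlation). Ribosomal protein genes rose by a median of 0.75, with 73 of 74 higher (camera adjusted p = 4.99e-32, 0.407 with estimated correlation). With p adjusted over the list alone, 7 immediate early, 4 glucocorticoid-responsive, 0 mitochondrially encoded and 58 ribosomal genes passed. No gene passed over all genes tested with edgeR, 2964 had an unadjusted p under 0.05 and DESeq2 called 540. The edgeR count was 1 without control replicate 3, and 1 with 2 surrogate variables in the model.

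At 5 d after reward conditioning, lists of energy and translation again rose in excitatory neurons. All 75 nuclear oxidative phosphorylation genes were higher than in the control, by a median log2 of 1.18 (camera adjusted p = 5.95e-44, 0.402 with estimated correlation). Ribosomal protein genes rose in 74 of 74 members by a median of 0.70 (camera adjusted p = 3.37e-27, 0.419 with estimated correlation). Excitatory synapse genes fell by a median of 0.23, with 28 of 30 lower (camera adjusted p = 5.65e-05, 0.402 with estimated correlation). Rbm3, an RNA-binding protein induced by cold, had 178 ± 22.8 CPM against 65.7 ± 4.14 (log2 1.44 ± 0.26; edgeR adjusted p = 0.0899), and Fdps, an enzyme of isoprenoid synthesis, 49.8 ± 7.66 against 20.8 ± 3.63. Fos differed by 0.22 ± 0.28, Arc by -0.47 ± 0.39, Npas4 by -0.29 ± 0.24, Bdnf by -0.62 ± 0.33 and Fkbp5 by -0.06 ± 0.14. Myelin genes, which neurons do not make, fell beside these lists by a median of 0.85 in 12 of 12 members (camera adjusted p = 0.00024, 0.652 with estimated correlation). Adjusted over the list alone, 71 oxidative phosphorylation, 48 ribosomal and 0 synapse genes passed. By edgeR 0 genes passed over all genes tested, with 3065 at unadjusted p under 0.05 and 696 by DESeq2. With the other 9 libraries left out of the fit the edgeR count was 809.

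Changes after fear and reward share 3 controls and were compared. Across 19030 genes at 2 h, which are not independent replicates, their covariance was 0.106 (Pearson r = 0.638), against 0.0575 on average and 0.0619 at most in 50 simulations of unchanged groups with shared controls (r = 0.482 on average and 0.506 at most). At 5 d the covariance was 0.107 (r = 0.549), against 0.0577 on average and 0.0614 at most (r = 0.498 and 0.520). The excess over the simulated mean depended on single controls. It was 0.0484 at 2 h and 0.0495 at 5 d, and 0.0293 and 0.0232 without control replicate 1, 0.0668 and 0.0601 without 2, and 0.0236 and 0.0479 without 3. At 5 d r was 0.552 without control replicate 1, under the lowest simulated 0.571, and 0.607 without replicate 3, against 0.611 on average. Shifts of whole libraries were not tested as a source of covariance.

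Fear and reward were set against each other directly at each time, to ask which differences depend on the outcome learned. At 2 h, Gadd45g, a DNA-damage and activity-induced regulator (chromosome 13, 51846678 to 51848468), had 29.5 ± 3.2 CPM after fear and 13 ± 0.821 after reward in excitatory neurons (log2 1.18 ± 0.17; edgeR adjusted p = 0.0684). Immediate early genes were higher after fear by a median of 0.30, in 21 of 26 members (camera adjusted p = 1.2e-08, 0.402 with estimated correlation); Npas4 differed by 1.48 ± 0.24 and Arc by 1.74 ± 0.40. Mitochondrially encoded genes were higher beside them by a median of 1.38 in 13 of 13 members (camera adjusted p = 4.77e-21, 0.402 with estimated correlation). At 5 d, immediate early genes were lower after fear by a median of 0.45, in 24 of 26 members (camera adjusted p = 7.79e-09, 0.402 with estimated correlation); Fos had 22.6 ± 7.57 CPM against 53.6 ± 9.45. Myelin genes were higher after fear at 5 d by a median of 1.22 in 12 of 12 members (camera adjusted p = 3.81e-10, 0.416 with estimated correlation). Adjusted over the list alone, 4 immediate early and 8 mitochondrially encoded genes passed at 2 h, and 8 immediate early and 6 myelin genes at 5 d. Over all genes tested edgeR called 0 at 2 h (572 at unadjusted p under 0.05; DESeq2 6) and 0 at 5 d (1598; DESeq2 5). At 2 h the edgeR count was 1 with RLE normalization and 2 without the low-count filter.

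The 5 d and 2 h groups of each kind of conditioning were compared to ask what changes with time. Gadd45g rose in excitatory neurons from 13 ± 0.821 CPM at 2 h after reward to 30.9 ± 4.35 at 5 d (log2 1.25 ± 0.17; edgeR adjusted p = 0.0319), higher in 3 of 3 libraries than in any of the earlier ones. It was 1 of 19027 genes called (585 at unadjusted p under 0.05; DESeq2 4). Immediate early genes rose with it, by a median of 0.30 in 16 of 26 members (camera adjusted p = 3.23e-08, 0.402 with estimated correlation), 1 past the threshold over all genes and 7 over the list alone. All 17 cholesterol synthesis genes were higher at 5 d after reward, by a median of 0.46 (camera adjusted p = 2.42e-13, 0.402 with estimated correlation), as were 13 of 13 mitochondrially encoded genes by 0.88 (camera adjusted p = 2.36e-07, 0.522 with estimated correlation). After fear the immediate early genes fell from 2 h to 5 d by a median of 0.42, in 24 of 26 members (camera adjusted p = 3.56e-12, 0.402 with estimated correlation). Glucocorticoid-responsive genes fell over the same interval by 0.30 in 14 of 15 members (camera adjusted p = 2.2e-05, 0.402 with estimated correlation), a call lost without fear 2 h replicate 2 (p = 0.214). Mitochondrially encoded genes fell beside both by 0.88 in 13 of 13 members (camera adjusted p = 7.21e-10, 0.457 with estimated correlation). By edgeR 0 single genes passed over that interval after fear (825 at unadjusted p under 0.05; DESeq2 13). The Gadd45g call ended without reward 2 h replicate 1, 2 or 3 (edgeR adjusted p = 0.260, 0.335 and 0.367) and without reward 5 d replicate 1 or 3 (0.295 and 0.216). It also ended with only the 6 libraries compared (0.218), with doublets kept (0.103), in the largest cluster of the class alone (0.163) and with 2 surrogate variables in the model (0.0806).

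**Figure D1:**
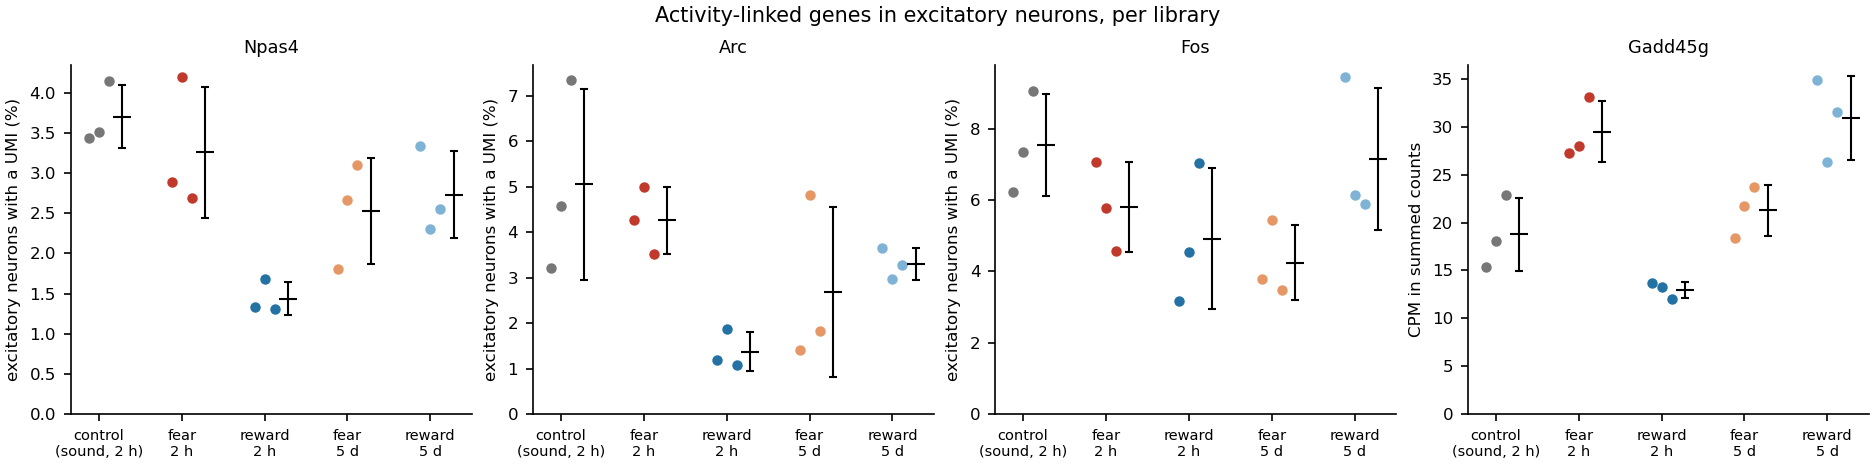
Percent of excitatory neurons with a UMI of Npas4, Arc or Fos after thinning to 2000 UMIs per cell, and CPM of Gadd45g in summed counts, for each of the 15 libraries (points) with the group mean and SD (bars). Npas4 was found in 1.44% of cells at 2 h after reward and 3.70% in the control, and Gadd45g rose from 13 to 30.9 CPM between 2 h and 5 d after reward.

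Single neurons were also scored for a UMI of each activity gene after thinning every cell to 2000 UMIs, to ask how many cells carry the mark. Npas4 was found in 3.70% ± 0.391 of excitatory neurons in the control, 3.26% ± 0.816 at 2 h after fear, 1.44% ± 0.208 at 2 h after reward, 2.52% ± 0.660 at 5 d after fear and 2.73% ± 0.543 at 5 d after reward. These shares differed between the groups (permutation p = 0.00723; adjusted p = 0.0434). Oligodendrocytes, which do not express Npas4, gave 0.122% to 0.271% in the group means at the same depth. Arc was found in 5.05% ± 2.10 of control and 1.37% ± 0.427 of reward 2 h excitatory neurons (permutation p = 0.0464; adjusted p = 0.139), against 3.41% to 5.34% of oligodendrocytes. Oligodendrocytes exceeded excitatory neurons in 3 of 5 groups, so they give no background level for Arc. Fos ranged from 4.24% ± 1.06 at 5 d after fear to 7.54% ± 1.43 in the control (permutation p = 0.128; adjusted p = 0.205), against 2.81% to 5.02% of oligodendrocytes. In inhibitory neurons none of the 3 genes passed (permutation p = 0.288 for Fos, 0.238 for Arc and 0.137 for Npas4). Pairs of groups were compared by exact permutation, whose smallest p is 0.1; Npas4 reached it in 5 of 8 comparisons: reward at 2 h against the control, fear at 2 h and reward at 5 d, and fear and reward at 5 d against the control. The Npas4 call ended without thinning (adjusted permutation p = 0.333). It also ended without control replicate 2 (0.0846) or 3 (0.113), fear 2 h replicate 1 (0.0586), reward 2 h replicate 1 (0.152), 2 (0.0958) or 3 (0.157), or reward 5 d replicate 2 (0.0597) or 3 (0.0774). Arc passed without control replicate 1 (0.0443) or fear 5 d replicate 2 (0.0364).

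In inhibitory neurons the same 4 comparisons with the control asked whether interneurons and other GABA neurons change as well. Nuclear oxidative phosphorylation genes rose by medians of 1.15 and 0.69 at 2 h after fear and reward, and of 0.78 and 1.13 at 5 d (camera adjusted p = 7.88e-57, 2.62e-34, 4.29e-30 and 1.42e-48; adjusted p = 0.402, 0.416, 0.457 and 0.402 with an estimated correlation). Atp5e, the epsilon subunit of the ATP synthase, had 265 ± 85.7 CPM at 2 h after fear against 96.4 ± 13.1 (log2 1.46 ± 0.27; edgeR adjusted p = 0.150). Immediate early genes fell by 0.58 at 2 h after reward, in 24 of 26 members (camera adjusted p = 2.37e-09, 0.402 with estimated correlation), and by 0.48 at 5 d after fear, in 23 of 26 (camera adjusted p = 2.37e-06, 0.457 with estimated correlation). Npas4 differed by -1.07 ± 0.31 and Arc by -1.2 ± 0.39 at 2 h after reward, and Fos by -1.06 ± 0.33 at 5 d after fear. Mitochondrially encoded genes fell beside them at 2 h after reward by 1.32 in 13 of 13 members (camera adjusted p = 7.04e-13, 0.407 with estimated correlation). Neuropeptide genes, such as those for somatostatin and neuropeptide Y, rose by 0.87 at 2 h after fear in 13 of 14 members (camera adjusted p = 0.000574, 0.407 with estimated correlation), by 0.82 at 2 h after reward in 11 (0.00421, 0.488 with estimated correlation) and by 0.93 at 5 d after reward in 12 (0.00719, 0.506 with estimated correlation). At 5 d after reward the direction turned with 2 surrogate variables (camera adjusted p = 0.741). At 2 h after fear heat shock genes rose beside them by 0.36 in 15 of 21 (camera adjusted p = 0.0103, 0.540 with estimated correlation), 6 higher and 1 lower over the list alone, a call lost without control replicate 1 or fear 2 h replicate 3 (up to p = 0.110). Adjusted over the list alone, 67, 37, 50 and 71 oxidative phosphorylation genes passed in the 4 comparisons, 0 and 2 immediate early genes, 10 mitochondrially encoded genes and 1, 0 and 0 neuropeptide genes. EdgeR called 0 of 17386 genes in each comparison, with 1715, 1299, 2424 and 2610 at unadjusted p under 0.05 and 287, 1, 260 and 567 by DESeq2. The edgeR count at 2 h after fear was 488 without fear 2 h replicate 2 and 13 in the largest cluster; at 5 d after reward it was 357 with only the 6 libraries compared and 129 in the largest cluster.

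**Figure D2:**
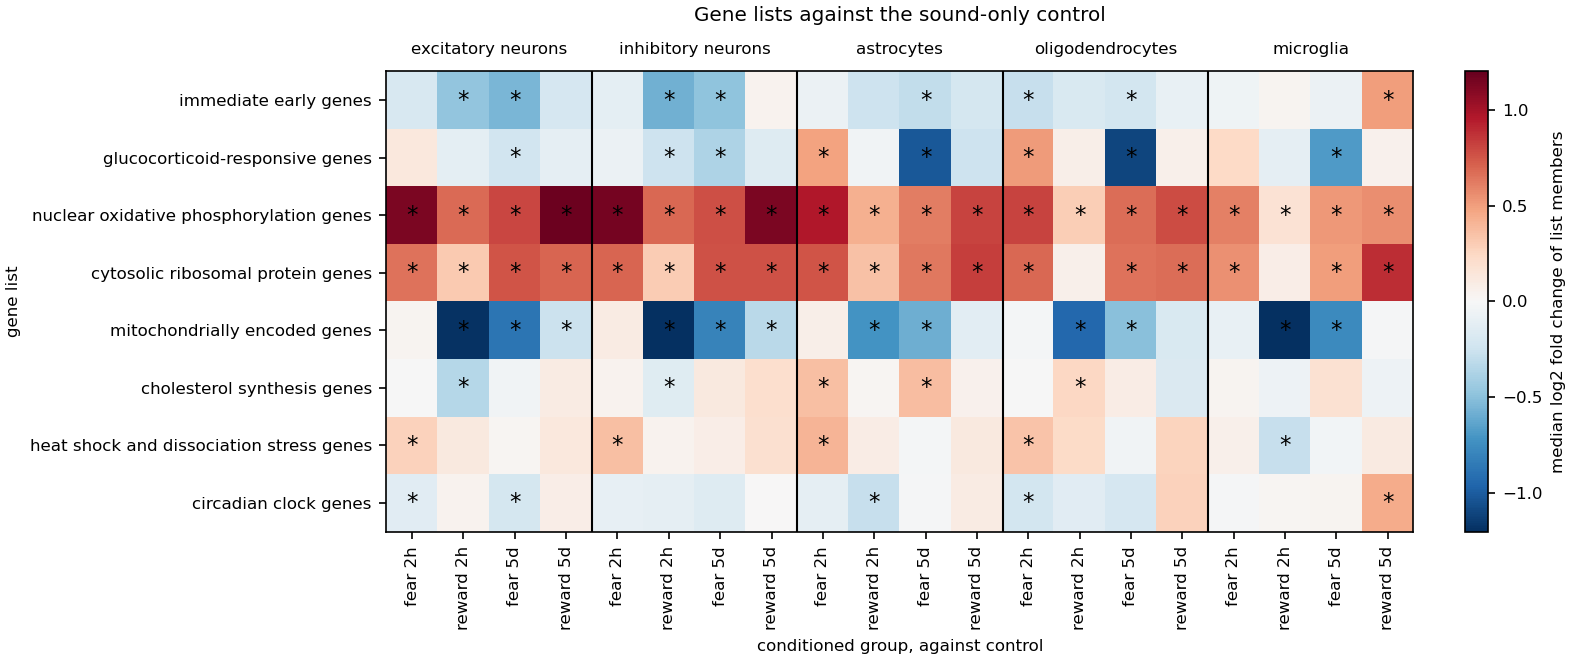
Median log2 change of the members of 8 gene lists (colour) in 5 cell classes for each conditioned group against the control; an asterisk marks a list called by camera with the preset correlation. Nuclear oxidative phosphorylation genes were higher in all 20 columns, from 0.17 to 1.18.

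Astrocytes at 2 h after reward conditioning carried the largest set of called genes against the control, 23 higher and 35 lower of 15213 tested with edgeR (1873 at unadjusted p under 0.05; DESeq2 215), 13 of them predicted genes. Ppp1r3g, which targets a phosphatase to glycogen (chromosome 13, 35958839 to 35970388), fell from 87.2 ± 10.2 to 27.6 ± 9.74 CPM (log2 -1.67 ± 0.23; edgeR adjusted p = 0.00851). Gcnt4, a glycan-branching enzyme, fell from 42.8 ± 7.54 to 14 ± 1.53 CPM, and Fam184b from 51.9 ± 3.89 to 20.1 ± 2.98 (both edgeR adjusted p = 0.00851). Larger falls at lower levels were those of Gpr35, an orphan receptor (log2 -2.02 ± 0.34), the integrin Itga10 (-1.86 ± 0.39), Afmid of tryptophan breakdown (-1.81 ± 0.27) and the salt-inducible kinase Sik1 (-1.75 ± 0.35). Lncbate1, a long noncoding RNA, rose most (log2 3.12 ± 0.52; 10.2 ± 2.73 CPM against 1.17 ± 0.420), followed by the decoy receptor Il1r2 (2.73 ± 0.50), Rtp1 (2.38 ± 0.45), Kif4 (2.23 ± 0.40) and Parvaos (2.21 ± 0.32). Gadd45g rose from 43.2 ± 2.96 to 70.6 ± 9.56 CPM (log2 0.70 ± 0.14; edgeR adjusted p = 0.0436). Interferon-response genes rose by a median of 0.34 in 5 of 6 members (camera adjusted p = 0.0351, 0.402 with estimated correlation), with Rsad2 (log2 2.05 ± 0.37) past the threshold over all genes and as the only member adjusted over the list alone. That call was lost without control replicate 2 or reward 2 h replicate 3 (up to 0.139). Mitochondrially encoded genes fell by 0.72 in 13 of 13 members (camera adjusted p = 3.73e-06, 0.540 with estimated correlation), 1 of them over the list alone. All 58 genes separated the 3 libraries of one group from the 3 of the other. The count was 6, 9 and 8 without control replicates 1, 2 and 3, and 0, 15 and 20 without reward 2 h replicates 1, 2 and 3. Every call named here ended without reward 2 h replicate 1. Ppp1r3g, Gcnt4 and Fam184b kept theirs without each of the other 5 libraries, and the other genes lost theirs without 1 to 5 more. It was 0 without the 2 controls rich in low-UMI barcodes, 99 without the low-count filter, 490 with only the 6 libraries compared and 105 with 2 surrogate variables.

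At 2 h after fear conditioning no astrocyte gene passed in edgeR (1555 at unadjusted p under 0.05; DESeq2 274), although several lists moved. Heat shock and dissociation stress genes rose by a median of 0.41 in 16 of 21 members (camera adjusted p = 7.14e-06, 0.402 with estimated correlation). Genes of cholesterol synthesis, which astrocytes carry out for neurons, rose by 0.36 in 17 of 17 members (camera adjusted p = 4e-06, 0.506 with estimated correlation); Fdps had 84.5 ± 8.16 CPM against 38.6 ± 4.77 (log2 1.13 ± 0.18; edgeR adjusted p = 0.0519). Glucocorticoid-responsive genes rose by 0.48 in 14 of 15 members (camera adjusted p = 0.0002, 0.522 with estimated correlation), a call lost without fear 2 h replicate 2 (p = 0.0797). Gadd45g had 79.7 ± 7.90 CPM against 43.2 ± 2.96 (log2 0.88 ± 0.14; edgeR adjusted p = 0.0519), Fkbp5 differed by 0.99 ± 0.52, and Gfap, the filament of reactive astrocytes, by 0.31 ± 0.34 after fear and -0.32 ± 0.34 after reward. Adjusted over the list alone, 11 heat shock, 5 cholesterol and 4 glucocorticoid-responsive genes passed. Without fear 2 h replicate 2 the edgeR count was 236; it was 8 without the low-count filter, 3 with at least 1000 genes per barcode and 6 with 2 surrogate variables.

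The genes that fell in astrocytes at 5 d after fear conditioning included 2 targets of the glucocorticoid receptor. Glucocorticoid-responsive genes fell by a median of 1.02 in 14 of 15 members (camera adjusted p = 1.12e-09, 0.402 with estimated correlation), 2 past the threshold over all genes and 10 over the list alone. Those were Plin4, a lipid droplet coat protein (log2 -2.27 ± 0.43; edgeR adjusted p = 0.0452), and Hif3a, an inhibitor of the hypoxia response, which fell from 175 ± 44.9 to 60.3 ± 8.38 CPM (log2 -1.54 ± 0.24; edgeR adjusted p = 0.0157). Fkbp5 had 5.17 ± 3.31 CPM against 40.4 ± 29.6 (log2 -3.02 ± 0.63; edgeR adjusted p = 0.0737), and Gfap differed by -0.20 ± 0.34. The largest fall was that of Pde10a (chromosome 17, 8525372 to 8986648), from 538 ± 436 to 37.7 ± 9.79 CPM (log2 -3.83 ± 0.50; edgeR adjusted p = 0.00516). It is a striatal neuron gene whose mean was 799 CPM at 2 h after fear, 237 at 2 h after reward and 68.4 at 5 d after reward. The exchanger Slc24a4 (-2.88 ± 0.49), the protease Adamts20 (-2.65 ± 0.40) and the Myc relative Mycl (-1.86 ± 0.31) fell. Cdk5rap3 (1.02 ± 0.18), the D-aspartate oxidase Ddo (0.94 ± 0.16) and Haghl (0.90 ± 0.16) rose. Cholesterol synthesis genes rose by 0.37 in 16 of 17 members (camera adjusted p = 0.000216, 0.588 with estimated correlation), 2 of them over the list alone, a call lost without fear 5 d replicate 2 (p = 0.0833). Of the genes tested, edgeR called 3 higher and 18 lower (2067 at unadjusted p under 0.05; DESeq2 302), 1 a predicted gene and all separated 3 from 3. The count was 4 and 10 without control replicates 1 and 2, 0, 130 and 8 without fear 5 d replicates 1, 2 and 3, 75 without the low-count filter, 11 with only the 6 libraries compared, 55 in the largest cluster and 118 with 2 surrogate variables. Without fear 5 d replicate 1 no call stood (Pde10a edgeR adjusted p = 0.0653, Hif3a 0.107). Hif3a also lost its call without control replicate 1 (0.156), and the other genes lost theirs without 2 to 4 more libraries.

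Astrocytes at 5 d after reward conditioning gave 0 called genes by edgeR against the control (1711 at unadjusted p under 0.05; DESeq2 207). Ribosomal protein genes rose by a median of 0.83 in 73 of 74 members (camera adjusted p = 1.51e-38, 0.402 with estimated correlation) and 61 over the list alone. Excitatory synapse genes, a sign of neuronal RNA in glia, fell by 0.48 in 28 of 30 members (camera adjusted p = 5.99e-06, 0.506 with estimated correlation), 0 of them over the list alone. Pde10a had 68.4 ± 18.3 CPM against 538 ± 436 (log2 -2.98 ± 0.47; edgeR adjusted p = 0.176), Gfap differed by 0.11 ± 0.34 and Fkbp5 by -0.31 ± 0.53. The edgeR count was 1 without control replicate 2, 2 without the low-count filter, 1 without the 2 controls rich in low-UMI barcodes and 1 with 2 surrogate variables.

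**Figure D3:**
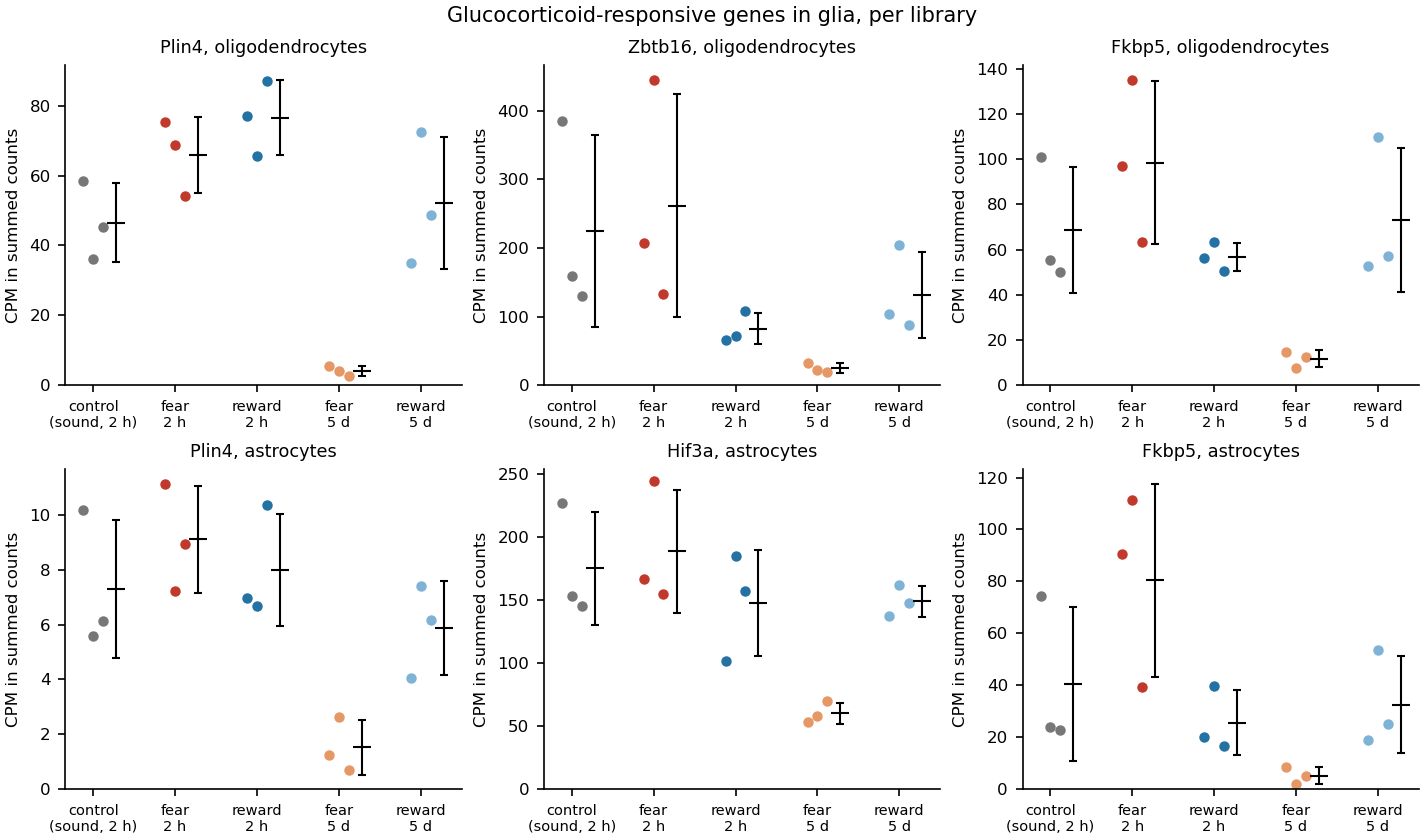
CPM of glucocorticoid-responsive genes in summed counts of oligodendrocytes (Plin4, Zbtb16, Fkbp5) and astrocytes (Plin4, Hif3a, Fkbp5), for each library (points) with the group mean and SD (bars).

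Oligodendrocytes, the cells that make myelin, showed the clearest single-gene change at 5 d after fear conditioning. Plin4 (chromosome 17, 56100591 to 56109803) fell from 46.6 ± 11.2 to 4.04 ± 1.43 CPM (log2 -3.53 ± 0.31; edgeR adjusted p = 5.96e-05) and stayed past the threshold in all 16 alternatives, with a highest adjusted p of 0.00188. Zbtb16, a transcription factor induced by glucocorticoids, fell from 225 ± 140 to 24.6 ± 7.11 CPM (log2 -3.19 ± 0.50; edgeR adjusted p = 0.0202). Fkbp5, a chaperone of the glucocorticoid receptor (chromosome 17, 28399094 to 28517527), fell from 68.8 ± 27.9 to 11.6 ± 3.74 CPM (log2 -2.57 ± 0.37; edgeR adjusted p = 0.0107). All 14 glucocorticoid-responsive genes were lower, by a median of 1.10 (camera adjusted p = 6.06e-12, 0.402 with estimated correlation), 3 past the threshold over all genes and 8 over the list alone. Col23a1 (-1.44 ± 0.25), the RNA polymerase III subunit Polr3e (-1.44 ± 0.24), the zinc finger factor Plagl1 (-1.39 ± 0.18) and Map7d2 (-1.33 ± 0.19) fell as well, and Hmg20b (0.97 ± 0.15) and Ilvbl (0.95 ± 0.16) rose. Mbp, the basic protein of myelin, differed by 0.03 ± 0.19. EdgeR called 3 higher and 8 lower of 14315 genes (2287 at unadjusted p under 0.05; DESeq2 546), all separated 3 from 3 and 2 of them predicted. The count was 1 and 6 without control replicates 1 and 2, 5, 450 and 2 without fear 5 d replicates 1, 2 and 3, 224 without the low-count filter, 140 with the replicate number as a block, 6 with only the 6 libraries compared and 1396 with 2 surrogate variables. Zbtb16 lost its call without control replicate 1 (edgeR adjusted p = 0.115) or fear 5 d replicate 1 (0.0754) or 3 (0.193), Fkbp5 without control replicate 1 (0.0762) or fear 5 d replicate 3 (0.1), and Map7d2 without control replicate 1 (0.0762). The other genes named lost theirs without 2 to 5 of the libraries.

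In oligodendrocytes at 5 d after reward conditioning 4 genes fell and 0 rose by edgeR (1651 at unadjusted p under 0.05; DESeq2 243). These were Rab7b, a GTPase of endosomes (16.4 ± 1.96 to 4.72 ± 0.454 CPM; log2 -1.80 ± 0.21; edgeR adjusted p = 0.00410), the collagen Col23a1 (-1.74 ± 0.26), Pdzrn3 (-1.55 ± 0.21) and Fam107b (-1.12 ± 0.17). Glucocorticoid-responsive genes gave no call there, and Fkbp5 differed by 0.09 ± 0.33 and Mbp by -0.15 ± 0.19. The count was 1 and 2 without control replicates 1 and 2 and 2, 0 and 1 without reward 5 d replicates 1, 2 and 3; Rab7b lost its call without reward 5 d replicate 2 (edgeR adjusted p = 0.0790). It was 47 without the low-count filter, 2 with the replicate number as a block, 2 with only the 6 libraries compared and 1 without the 2 controls rich in low-UMI barcodes.

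At 2 h after fear conditioning, heat shock genes rose in oligodendrocytes by a median of 0.34 in 15 of 21 members (camera adjusted p = 0.0048, 0.453 with estimated correlation), 4 over the list alone. Clock genes fell by 0.22 in 12 of 16 members (camera adjusted p = 0.00664, 0.402 with estimated correlation), 0 over the list alone, a call lost without fear 2 h replicate 1 (p = 0.143). At 2 h after reward, the linker histone gene H1f0 had 207 ± 22.1 CPM against 70.8 ± 13.9 (log2 1.55 ± 0.25; edgeR adjusted p = 0.0579). Mitochondrially encoded genes fell there by 0.95 in 13 of 13 members (camera adjusted p = 5.35e-12, 0.402 with estimated correlation), 8 over the list alone. Mbp differed by 0.02 ± 0.19 after fear and -0.25 ± 0.19 after reward, and Fkbp5 by 0.52 ± 0.33 and -0.28 ± 0.33. EdgeR called 0 genes after fear (1235 at unadjusted p under 0.05; DESeq2 218) and 0 after reward (1151; DESeq2 60). After fear the count was 178 without fear 2 h replicate 2 and 67 without the low-count filter; after reward it was 16 without that filter, 53 with only the 6 libraries compared and 43 with 2 surrogate variables.

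Microglia, the immune cells of brain tissue, were compared with the control in all 4 conditioned groups. Reactive microglia and cytokine genes rose at 5 d after reward by a median of 0.60 in 11 of 14 members (camera adjusted p = 0.000469, 0.522 with estimated correlation), 4 over the list alone. Immediate early genes, which dissociation can induce, rose beside them by 0.50 in 20 of 25 (camera adjusted p = 0.00250, 0.667 with estimated correlation), 4 over the list alone, a call lost without reward 5 d replicate 1 (p = 0.0769). Apoe, a lipid carrier of reactive microglia, had 698 ± 325 CPM against 238 ± 37.5 (log2 1.55 ± 0.35; edgeR adjusted p = 0.466); its difference was 1.26 ± 0.35 at 2 h and 1.14 ± 0.35 at 5 d after fear, and 0.95 ± 0.35 at 2 h after reward. P2ry12, a receptor of resting microglia, differed by -0.21 ± 0.29, 0.05 ± 0.29, -0.08 ± 0.29 and 0.28 ± 0.29 in fear at 2 h and 5 d and reward at 2 h and 5 d. Glucocorticoid-responsive genes fell at 5 d after fear by a median of 0.68 in 8 of 12 members (camera adjusted p = 0.000833, 0.402 with estimated correlation), 3 over the list alone; Tsc22d3 had 52.1 ± 18.8 CPM against 168 ± 65.9 (log2 -1.69 ± 0.33; edgeR adjusted p = 0.305). Excitatory synapse genes, a sign of neuronal RNA, fell at 5 d after reward by 0.63 in 29 of 29 members (camera adjusted p = 1.28e-09, 0.609 with estimated correlation), 0 over the list alone. EdgeR called 0 of 13878 genes in fear at 2 h, reward at 2 h, fear at 5 d and reward at 5 d, with 563, 474, 1020 and 1019 at unadjusted p under 0.05 and 14, 0, 14 and 95 by DESeq2. Without the low-count filter the counts were 14, 0, 4 and 11, with 2 surrogate variables 0, 1, 11 and 0, and with only the 6 libraries compared 0, 0, 0 and 1.

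The labelling viruses left 3 reporter transcripts in the count tables: EGFP, mCherry and EYFP. The labels do not say which reporter marks which projection, so results are given by reporter. At least 1 EGFP UMI was found in 79.7% ± 13.7 of excitatory neurons (mean and SD over 15 libraries; median depth 13180 UMIs per cell) and in 61.0% ± 20.8 of oligodendrocytes (3780 UMIs), so much of the EGFP share is background. For mCherry the shares were 41.6% ± 17.9 and 15% ± 10.9, and for EYFP 20.4% ± 10.9 and 6.30% ± 6.55. Above the level that about 1 in 1000 oligodendrocytes of the same library exceeds, EGFP marked 32.6% ± 7.82 of excitatory neurons, mCherry 23.1% ± 9.46 and EYFP 9.51% ± 3.96. The same level was passed by 1.85%, 1.23% and 0.438% of inhibitory neurons. Of 8391 EGFP and 5818 mCherry excitatory neurons, 2452 carried both. Between 65.0% and 94.2% of EYFP neurons per library also carried EGFP. The EGFP and EYFP sequences are near identical and misassigned reads were not tested for, so EYFP is not read as a label of its own. EGFP was frequent in excitatory clusters 5 (59.0%) and 11 (57.1%), where mCherry reached 30.4% and 30.6%; cluster 26 had 42.9% mCherry and 7.52% EGFP.

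**Figure D4:**
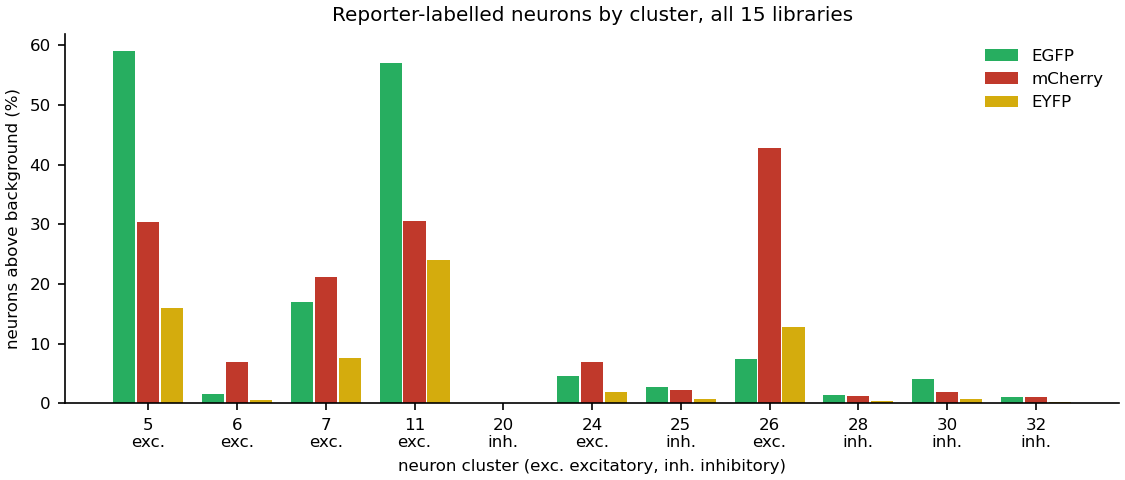
Percent of neurons in each neuron cluster with EGFP, mCherry or EYFP above the oligodendrocyte background of their library, with the cells of all 15 libraries pooled. Inhibitory clusters stayed at or under 4.12%. Within libraries EGFP was highest in cluster 5 in 10 and in cluster 11 in 5 of 15. For mCherry cluster 26 was highest in 9 of the 11 libraries where it had at least 20 cells, and inhibitory clusters reached up to 9.95%.

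Labelled and unlabelled neurons of the same library were compared. With at least 1 UMI as the label, EGFP neurons had 3623 genes higher and 3605 lower of 16906, mCherry neurons 4192 and 3551 of 16947, and EYFP neurons 4879 and 4035 of 17892 (edgeR with the library as a block). Dcn, a matrix proteoglycan, rose most with EGFP (log2 2.52 ± 0.10, higher in 15 of 15 libraries), and Foxp2, a transcription factor of inhibitory neurons, fell by 1.2 ± 0.06. With mCherry, Grp, a peptide of excitatory neurons, was higher by 1.43 ± 0.14, and Vip and Crh, peptides of interneurons, fell by 1.76 ± 0.24 and 1.51 ± 0.16. These sums mix excitatory and inhibitory neurons. Of 6967 EGFP and 7261 mCherry genes called this way and tested among excitatory neurons above background, 5135 and 2233 were called again, 428 and 193 of these with the opposite sign. Called or not, 1000 and 1459 had the other direction. With labels above background the count was 11296 for EGFP, 8100 for mCherry and 9436 for EYFP. With that label, counts among excitatory neurons and in cluster 5 were 8850 and 6734 for EGFP, 2976 and 2299 for mCherry and 7414 and 6686 for EYFP.

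Excitatory neurons with mCherry alone were then set against those with EGFP alone, a contrast chosen after the data had been seen. Of 13306 genes 2225 were higher with mCherry and 2269 higher with EGFP (edgeR with the library as a block). Higher with mCherry were the collagen Col11a1 (log2 3.28 ± 0.25), the contactin partner Cntnap3 (3.18 ± 0.25), the growth factor Ccn2 (3.08 ± 0.23) and the nicotinic receptor modulators Lypd6 (3 ± 0.19) and Lypd6b (2.94 ± 0.21), each in 15 of 15 libraries (edgeR adjusted p at most 9.38e-08). Higher with EGFP in 15 of 15 libraries were Olig3 (-3.91 ± 0.37), the fatty acid transporter Cd36 (-3.60 ± 0.16), Dcn (-3.44 ± 0.18; 6.08 ± 6.61 against 61.9 ± 32.5 CPM) and the calcium buffer Calb2 (-2.54 ± 0.19; 29.0 ± 21.2 against 165 ± 91.6 CPM). Among immediate early genes 10 of 24 were higher with mCherry and 4 lower, led by Nr4a2 (2.02 ± 0.21; 474 ± 254 against 110 ± 39.2 CPM). Neuromodulator receptor genes split, with 6 of 21 higher, such as the serotonin receptor Htr2a (1.87 ± 0.15), and 5 lower, such as the cannabinoid receptor Cnr1 (-0.85 ± 0.10). Circadian clock genes were higher in 14 of 16 members and lower in 1, and 13 of 13 mitochondrially encoded genes were lower, by a median of 0.53. Adjusted over the list alone, these lists gave 10 and 5, 6 and 5, 14 and 1, and 0 and 13 higher and lower. The 2 populations differ in their share of clusters, which this contrast does not remove. In cluster 5 alone 4096 of the genes were tested, 431 had the other direction and 2619 were called again, 2501 of them with the same sign. Nr4a2 turned there (-1.66; edgeR adjusted p = 0.000576), while Cd36, Dcn, Calb2, Htr2a and Cnr1 kept their sign and call. The other genes named here were not tested there.

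Conditioning was compared within labelled excitatory neurons, a set of tests added after the data had been seen. Gadd45g was higher at 2 h after fear than after reward in EGFP neurons (32.5 ± 0.741 against 13.3 ± 1.38 CPM; log2 1.29 ± 0.16; edgeR adjusted p = 0.00583). It rose from 2 h to 5 d after reward in EGFP neurons by 1.14 ± 0.15 (edgeR adjusted p = 0.0240) and in mCherry neurons by 1.66 ± 0.24 (adjusted p = 0.0357). It was the only gene called in each of the 3 tests, of 16136 with EGFP (560 and 461 at unadjusted p under 0.05; DESeq2 4 and 2) and 15372 with mCherry (533; DESeq2 3). For fear against reward at 2 h in mCherry neurons edgeR called 0 (718 at unadjusted p under 0.05; DESeq2 6), and Gadd45g had a log2 difference of 1.52 ± 0.24 (adjusted p = 0.0667). Npas4 differed by 1.85 ± 0.29 between fear and reward at 2 h in EGFP neurons (edgeR adjusted p = 0.0840). At 2 h with EGFP the call ended without reward 2 h replicate 2 (0.133) or 3 (0.0656) and the count was 2 without fear 2 h replicate 2 or 3; with mCherry it was 2 without fear 2 h replicate 1 and 1 without reward 2 h replicate 3. From 2 h to 5 d after reward both calls ended without reward 2 h replicate 1, 2 or 3 or reward 5 d replicate 1 or 3, with an adjusted p of 0.0994 to 0.452 for EGFP and 0.206 to 0.399 for mCherry. With only the 6 libraries compared, both EGFP calls ended (edgeR adjusted p = 0.411 at 2 h and 0.633 over time after reward). Over time after reward the calls also ended with 2 surrogate variables (0.0633 for EGFP and 0.0528 for mCherry), and for mCherry with the replicate number as a block (0.0900).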

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

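All tests in this part were chosen after the results were seen, except the test of a shift of whole libraries shared by the cell classes and the planned comparisons whose counts are set against other splits. The change from 2 h to 5 d after fear less the change after reward was tested as an interaction.

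In excitatory neurons Gadd45g went from 29.5 to 21.3 CPM after fear and from 13 to 30.9 after reward (log2 difference -1.72; edgeR adjusted p = 0.0412). It was the 1 gene called (737 at unadjusted p under 0.05), and 8 of 101 regroupings called as many, up to 68. In overlapping labelled subsets of these neurons, not regrouped, the difference was -1.74 with EGFP (edgeR adjusted p = 0.00909) and -2.27 with mCherry (0.0217). Gadd45b (-2.37; 0.00247) and Tiparp (-2.49; 0.0271) also passed with mCherry, and Ighm, an antibody gene at 0.418 to 3.27 CPM, with EGFP (4.06; 0.0133).

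In astrocytes 5 genes passed (1445 at unadjusted p under 0.05), and 7 of 101 regroupings called as many, up to 171. They were Sik1 (-3.34; edgeR adjusted p = 0.0111), Tekt4 (-2.71; 0.000843), Ppp1r3g (-2.29; 0.0111), Cebpd (-2.27; 0.0116) and Slc35e4 (-1.7; 0.0111). Ppp1r3g had 95.9 CPM at 2 h and 52.5 at 5 d after fear, and 27.7 and 74 after reward. In oligodendrocytes 5 genes passed (1056 at unadjusted p under 0.05), and 5 of 101 regroupings called as many (share 0.0495, up to 225). They were Zbtb16 (-4.1; edgeR adjusted p = 0.0436), Plin4 (-3.48; 0.00126), Fkbp5 (-3.46; 0.012), Polr3e (-2.97; 0.00126) and Map7d2 (-1.81; 0.012). EdgeR called 0 genes for the interaction in inhibitory neurons (543 at unadjusted p under 0.05), microglia (578), endothelial cells (665) and oligodendrocyte precursors (652); DESeq2 was not run for it.

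Nuclear oxidative phosphorylation and ribosomal protein genes had list medians above the control in the 5 classes of the planned tests, from 0.0567 to 1.18. Camera did not call the ribosomal list at 2 h after reward in oligodendrocytes (adjusted p = 0.679) or microglia (0.393), and with an estimated correlation it called 0 lists. Without the 2 controls with many low-UMI barcodes the list medians were 1.43 times those with all 3 (median of 40 ratios) and 40 of 40 stayed above 0. Those controls lowered all 40 medians, which without them rest on control replicate 1 alone. A shift of whole libraries remains a candidate explanation: the list means of excitatory neurons and astrocytes moved together over the 15 libraries, as deviations from their group (r = 0.891, permutation p = 0.00025, rho = 0.871, and 0.906 without the 2 farthest libraries; ribosomal genes r = 0.845, permutation p = 0.00029, rho = 0.832, and 0.825). Whether handling or biology moves whole libraries cannot be told apart here.

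Glucocorticoid-responsive genes were low at 5 d after fear in glia. Time since the session alone is argued against, since in oligodendrocytes the list lay at a median of -0.95 against reward at 5 d. Free RNA from 1 source stays open: 6 of 14 members lay over 2 standard errors off the best single oligodendrocyte to astrocyte ratio. The rest lay within. A signal reaching all classes, such as a lower hormone level, is a hypothesis. The list median lay under -0.2 in 7 of 7 classes between fear at 2 h and at 5 d. The list was itself raised at 2 h after fear (0.484 in astrocytes and 0.51 in oligodendrocytes). Against the control 7 of 7 classes also lay under -0.2 at 5 d after fear, and against reward at 5 d 6 of 7, with excitatory neurons at -0.0845. The labels give no hormone level or hour of sampling.

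Immediate early genes were low in neurons at 2 h after reward and 5 d after fear. A dissociation response of all cells is not excluded. Of 3 glial classes 1 had a list median under -0.2 at 2 h after reward and 2 at 5 d after fear (astrocytes -0.294, oligodendrocytes -0.222). Excitatory neuron and microglia list means gave r = 0.316 (permutation p = 0.305, rho = 0.282, 0.119 without the 2 farthest). Neuron subtype shifts were not tested.

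Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. In excitatory neurons edgeR called 0 genes at 2 h after fear (1996 at unadjusted p under 0.05; DESeq2 304) and 138 in the highest other split, which points to a structure of the samples. The same holds in inhibitory neurons (0 and 338; 1715 unadjusted; DESeq2 287), astrocytes (0 and 60; 1555; DESeq2 274), oligodendrocytes (0 and 401; 1235; DESeq2 218) and microglia (0 and 14; 563; DESeq2 14). Between fear and reward at 2 h in excitatory neurons the counts were 0 and 22 (572; DESeq2 6), and from 2 h to 5 d after fear 0 and 1 (825; DESeq2 13). From 2 h to 5 d after fear a split gave 201 against 55 real in astrocytes, where 3 of 10 splits called as many, 113 against 12 in oligodendrocytes, where 2 did, and 4 against 16 in endothelial cells. Astrocytes at 2 h after reward (58), 5 d after fear (21), fear against reward at 2 h (25) and 5 d (3), and oligodendrocytes at 5 d after fear (11), after reward (4) and between them (43) had 0 in the highest other split. In EGFP neurons the counts were 1 and 7 for fear against reward at 2 h, and 1 and 0 from 2 h to 5 d after reward, as in mCherry and all excitatory neurons.

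Lists called within a comparison numbered 3 to 12, and the highest other split called 7 to 16. In excitatory neurons the real and highest other counts were 10 and 9 at 2 h after reward, and 11 and 10 at 5 d after reward, where 1 of 10 splits was as large. They were 12 and 12 at 5 d after fear, and 7 and 11 at 2 h after fear, where 6 splits were as large. At 2 h after fear they were 4 and 14 in microglia, with 9 splits as large, and 7 and 14 in inhibitory neurons, with 5. In oligodendrocytes from 2 h to 5 d after fear they were 4 and 14, with 10 splits as large, and in inhibitory neurons at 5 d after reward 8 and 13, with 4. Labels exchanged within libraries called at most 0 genes for EGFP (7228 real), 4 for mCherry (7743), 2491 for EYFP (8914) and 8 for mCherry alone against EGFP alone (4494). Of 25 sets the real one called most. Cell clusters differ with labels, so projection was not tested.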

How the results depend on the processing

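The tests of the largest cluster of a class, of the 2 controls rich in low-UMI barcodes, of surrogate variables, of labels above background and of the replicate block with an estimated correlation were chosen after the results were seen, as were all comparisons of endothelial cells and labelled neurons and those of astrocytes and oligodendrocytes between conditioned groups. The other alternatives were chosen before the data were examined. The cause of a difference between settings was not tested. Counts below are genes called, and in groups of 4 they are for fear at 2 h, reward at 2 h, fear at 5 d and reward at 5 d against the control.

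With DESeq2 in place of edgeR the counts were 304, 26, 540 and 696 in excitatory neurons, 287, 1, 260 and 567 in inhibitory neurons, 274, 215, 302 and 207 in astrocytes, 218, 60, 546 and 243 in oligodendrocytes and 14, 0, 14 and 95 in microglia. Elsewhere that setting gave 6 for fear against reward at 2 h, 5 for fear against reward at 5 d, 13 for 5 d against 2 h after fear and 4 for 5 d against 2 h after reward in excitatory neurons, 187 for 5 d against 2 h after fear, 88 for fear against reward at 5 d and 144 for fear against reward at 2 h in astrocytes and 100 for 5 d against 2 h after fear and 190 for fear against reward at 5 d in oligodendrocytes. It gave 254 for fear at 5 d and 128 for 5 d against 2 h after fear in endothelial cells, 4 for fear against reward at 2 h and 2 for 5 d against 2 h after reward in EGFP neurons and 6 for fear against reward at 2 h and 3 for 5 d against 2 h after reward in mCherry neurons.

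Without the low-count filter the counts were 8, 99, 75 and 2 in astrocytes, 67, 16, 224 and 47 in oligodendrocytes and 14, 0, 4 and 11 in microglia. Elsewhere that setting gave 2 for fear against reward at 2 h in excitatory neurons, 94 for 5 d against 2 h after fear, 29 for fear against reward at 5 d and 63 for fear against reward at 2 h in astrocytes and 41 for 5 d against 2 h after fear and 106 for fear against reward at 5 d in oligodendrocytes. It gave 256 for fear at 5 d and 148 for 5 d against 2 h after fear in endothelial cells, 2 for fear against reward at 2 h in EGFP neurons and 2 for fear against reward at 2 h in mCherry neurons. With only the 6 libraries compared in the fit the counts were 0, 2, 0 and 809 in excitatory neurons, 0, 1, 0 and 357 in inhibitory neurons, 0, 490, 11 and 0 in astrocytes, 0, 53, 6 and 2 in oligodendrocytes and 0, 0, 0 and 1 in microglia. Elsewhere that setting gave 0 for 5 d against 2 h after reward in excitatory neurons, 10 for 5 d against 2 h after fear and 0 for fear against reward at 2 h in astrocytes and 6 for 5 d against 2 h after fear and 12 for fear against reward at 5 d in oligodendrocytes. It gave 2 for fear at 5 d and 0 for 5 d against 2 h after fear in endothelial cells and 0 for fear against reward at 2 h and 0 for 5 d against 2 h after reward in EGFP neurons. With RLE normalization the counts were 1 for fear against reward at 2 h in excitatory neurons. With doublets kept the counts were 0 for 5 d against 2 h after reward in excitatory neurons. With at least 1000 genes per barcode the counts were 3, 71, 24 and 0 in astrocytes.

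With the replicate number as a replicate block the counts were 0, 0, 140 and 2 in oligodendrocytes. Elsewhere that setting gave 5 for fear against reward at 5 d in astrocytes and 36 for 5 d against 2 h after fear and 73 for fear against reward at 5 d in oligodendrocytes. It gave 16 for fear at 5 d and 54 for 5 d against 2 h after fear in endothelial cells and 0 for 5 d against 2 h after reward in mCherry neurons. Deviations from the group mean of libraries with the same number had a median correlation of 0.103 in excitatory neurons, 0.0695 in inhibitory neurons, 0.0815 in astrocytes, 0.161 in oligodendrocytes and 0.128 in microglia. For other numbers it was -0.0503, -0.071, -0.0384, -0.11 and -0.059. Of 15 libraries 11, 8, 7, 9 and 8 were most like one of their own number, a hint from the data and not the design. The lowest correlations were -0.182, -0.262, -0.369, -0.397 and -0.459, so the numbers were not taken to pair the samples.

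In the largest cluster of each class alone the counts were 13, 0, 0 and 129 in inhibitory neurons and 0, 74, 55 and 0 in astrocytes. Elsewhere that setting gave 0 for 5 d against 2 h after reward in excitatory neurons and 16 for fear against reward at 2 h in astrocytes. Without the 2 controls rich in low-UMI barcodes the counts were 0, 0, 30 and 1 in astrocytes and 0, 0, 7 and 1 in oligodendrocytes. With 2 surrogate variables in the model the counts were 0, 0, 1 and 0 in excitatory neurons, 6, 105, 118 and 1 in astrocytes, 0, 43, 1396 and 6 in oligodendrocytes and 0, 1, 11 and 0 in microglia. Elsewhere that setting gave 0 for 5 d against 2 h after reward in excitatory neurons, 249 for 5 d against 2 h after fear, 11 for fear against reward at 5 d and 206 for fear against reward at 2 h in astrocytes and 132 for 5 d against 2 h after fear and 68 for fear against reward at 5 d in oligodendrocytes. It gave 633 for fear at 5 d and 170 for 5 d against 2 h after fear in endothelial cells, 0 for 5 d against 2 h after reward in EGFP neurons and 0 for 5 d against 2 h after reward in mCherry neurons.

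Leaving out each library in turn gave the following lowest and highest counts. In excitatory neurons they were 0 to 466 for fear at 2 h, 0 to 1 for fear at 5 d and 0 to 1 for 5 d against 2 h after reward. In inhibitory neurons they were 0 to 488 for fear at 2 h. In astrocytes they were 0 to 236 for fear at 2 h, 0 to 20 for reward at 2 h, 0 to 130 for fear at 5 d and 0 to 1 for reward at 5 d. They were 18 to 65 for 5 d against 2 h after fear, 3 to 29 for fear against reward at 5 d and 0 to 35 for fear against reward at 2 h in the same class. In oligodendrocytes they were 0 to 178 for fear at 2 h, 1 to 450 for fear at 5 d, 0 to 3 for reward at 5 d and 5 to 39 for 5 d against 2 h after fear. They were 3 to 131 for fear against reward at 5 d in the same class. In endothelial cells they were 0 to 79 for fear at 5 d and 0 to 41 for 5 d against 2 h after fear. In EGFP neurons they were 0 to 2 for fear against reward at 2 h and 0 to 1 for 5 d against 2 h after reward. In mCherry neurons they were 0 to 2 for fear against reward at 2 h and 0 to 1 for 5 d against 2 h after reward.

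Of 532 planned list tests camera called 180 with its preset correlation. It called 0 with an estimated correlation, fry called 0, and the replicate block with an estimated correlation gave 0, while the replicate block alone gave 192 and surrogate variables 161. Among the results tested 13 called lists changed direction with 2 surrogate variables, with the camera adjusted p given here. In excitatory neurons for fear against reward at 5 d these were nuclear oxidative phosphorylation genes (0.173), homeostatic microglia genes (0.696), reactive microglia and cytokine genes (0.771) and astrocyte transport and coupling genes (0.251). In inhibitory neurons for reward at 2 h these were glucocorticoid-responsive genes (0.935) and myelin genes (0.758). In inhibitory neurons for reward at 5 d it was neuropeptide genes (0.741). In astrocytes for fear against reward at 5 d it was excitatory synapse genes (0.533). In oligodendrocytes for reward at 5 d it was neuromodulator receptor genes (0.946). In oligodendrocytes for fear against reward at 5 d these were excitatory synapse genes (0.0416), inhibitory synapse genes (0.464) and neuromodulator receptor genes (0.428). In microglia for reward at 5 d it was inhibitory synapse genes (0.739). Of the other list alternatives 423 kept the call and 596 lost it.

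Among 343 named gene results, 118 of them called, 39 alternatives reversed the sign of a gene that was not called, 216 gained and 552 lost a call, and 4377 did neither, while 75 of these changed sign by a move within 1 standard error. In the largest cluster alone the reversed log2 values were 0.25 for Fos (fear at 2 h), 0.39 for Arc (fear at 2 h), 0.22 for Bdnf (reward at 2 h), 0.015 for Fos (reward at 2 h), -0.10 for Fos (reward at 5 d), 0.21 for Fkbp5 (reward at 5 d), 0.14 for Npas4 (fear against reward at 5 d), -0.12 for Fos (5 d against 2 h after reward) and 0.31 for Fkbp5 (5 d against 2 h after reward) in excitatory neurons. There followed -0.57 for Fos (fear at 2 h), 0.69 for Bdnf (fear at 5 d) and 0.13 for Fkbp5 (reward at 5 d) in inhibitory neurons. There followed -0.40 for Gfap (reward at 5 d) and 0.29 for Gfap (fear against reward at 5 d) in astrocytes. Without the 2 controls rich in low-UMI barcodes they were 0.35 for Arc (fear at 2 h) and -0.21 for Fkbp5 (fear at 2 h) in excitatory neurons. There followed -0.18 for Fkbp5 (fear at 2 h) in inhibitory neurons. There followed -0.076 for Fkbp5 (fear at 2 h) and -0.50 for Fkbp5 (reward at 5 d) in oligodendrocytes. With 2 surrogate variables they were -0.35 for Fos (fear at 2 h), 0.0604 for Fkbp5 (reward at 2 h), -0.43 for Fos (reward at 5 d) and 0.23 for Fkbp5 (reward at 5 d) in inhibitory neurons. There followed -0.10 for P2ry12 (reward at 5 d) in microglia. There followed 0.0797 for Gfap (fear against reward at 5 d) in astrocytes. Leaving out each library in turn, the log2 values of such genes spanned -0.40 to 0.26 for Fos (fear at 2 h), -0.43 to 0.32 for Arc (fear at 2 h), -0.24 to 0.22 for Npas4 (fear at 2 h) and -0.20 to 0.31 for Bdnf (fear against reward at 5 d) in excitatory neurons. The span was -0.33 to 0.35 for Fos (fear at 2 h) and -0.17 to 0.14 for Fkbp5 (fear at 2 h) in inhibitory neurons. The span was -0.0392 to 0.57 for Gfap (fear at 2 h), -1.13 to 0.14 for Fkbp5 (reward at 2 h), -0.25 to 0.37 for Gfap (reward at 5 d), -0.87 to 0.47 for Fkbp5 (reward at 5 d) and -0.52 to 0.0647 for Gfap (fear against reward at 5 d) in astrocytes. The span was -0.47 to 0.10 for Fkbp5 (reward at 2 h) and -0.33 to 0.48 for Fkbp5 (reward at 5 d) in oligodendrocytes. The span was -0.14 to 0.48 for Fos (fear against reward at 2 h) in EGFP neurons.

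The share of excitatory neurons with an Npas4 UMI had an adjusted permutation p of 0.333 without thinning, and of 0.0156 to 0.157 as each library was left out. For Arc the range was 0.0364 to 0.297, for the share of mural cells 0.0404 to 0.745 and for unnamed cells 0.0437 to 0.745. Labels above background gave 11296 genes for EGFP. With that label and also fewer cells, mCherry gave 2976 among excitatory neurons and 2299 in cluster 5. The percent of excitatory neurons with EGFP was 62.8 with at least 2 UMIs and 32.6 above background, and it was 23.1 for mCherry and 9.51 for EYFP above background.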

Other observations

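All comparisons between conditioned groups in this part were chosen after the results were seen.

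In astrocytes glucocorticoid-responsive genes fell from 2 h to 5 d after fear by a median of 1.64 in 15 of 15 members, 7 past the threshold over all genes and 13 over the list alone (camera adjusted p = 7.91e-24, 0.105 with estimated correlation). Fkbp5 fell from 80.4 to 5.17 CPM (log2 -4.01 ± 0.64; edgeR adjusted p = 0.00786), a call lost without fear 5 d replicate 2 (0.0520) or 3 (0.0577) and without the low-count filter (0.0755). In oligodendrocytes all 14 were lower by a median of 1.52, 3 of them past the threshold over all genes and 13 over the list alone (camera adjusted p = 7.53e-30, 0.105 with estimated correlation), and Plin4 fell from 66 to 4.04 CPM (log2 -4.03 ± 0.31; edgeR adjusted p = 1.01e-05). In endothelial cells Fkbp5 fell from 95.9 to 5.05 CPM (log2 -4.2 ± 0.54; edgeR adjusted p = 0.00659), a call lost without fear 5 d replicate 2 (0.0965) or 3 (0.0946) and with only the 6 libraries compared (0.0514); DESeq2 gave it no adjusted p. Between fear and reward at 5 d, Sgk1, a kinase induced by glucocorticoids, was at 62.1 ± 14.3 and 956 ± 434 CPM in oligodendrocytes (log2 -3.94 ± 0.68; edgeR adjusted p = 0.0244), a call lost without fear 5 d replicate 1 (0.123) or 3 (0.146), and also without reward 5 d replicate 2, without the low-count filter (0.109) or with 2 surrogate variables (0.156). At 2 h, astrocyte Sik1 was at 16.6 CPM after fear and 2.65 after reward (log2 2.66 ± 0.34; edgeR adjusted p = 0.00427), a call lost without reward 2 h replicate 1 (0.065) or 2 (0.0531) and with only the 6 libraries compared (0.0956).

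Choroid plexus genes had fewer than 5 tested members and were not tested. The reactive astrocyte genes gave 0 calls in 16 tests and the basolateral excitatory subtype genes 0 in 24 tests by camera. Late activity-response genes were called in 5 tests, homeostatic microglia genes in 6, inhibitory synapse genes in 3, neuromodulator receptor genes in 3, and astrocyte transport and coupling genes in 8. With an estimated correlation camera called 0 of the 532 list tests. Striatal projection neuron genes were called in 1 test, in excitatory neurons at 5 d after fear (camera adjusted p = 0.0375, 0.402 with estimated correlation), a call lost without control replicate 3 or fear 5 d replicate 2 (up to 0.211).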
